A study of Mus musculus with 14 samples.

How the data were processed

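Quadriceps muscle of male C57BL/6 mice aged 4 months was studied with HDAC3 wild type and HDAC3-depleted (knockout) animals. Of the 14 samples of the series, 8 entered the comparisons: 6 RNA-seq libraries taken at ZT10 in resting mice (3 wild type, 3 knockout) and 2 HDAC3 ChIP-seq libraries of wild-type muscle (1 at ZT10, 1 at ZT22). The knockout ChIP-seq library, the input libraries and the nascent-transcript (GRO-seq) libraries, 6 in all, were not analysed here. Groups and replicate numbers came from the labels. Nothing in the labels says whether replicates came from separate animals, so p-values of tests between libraries measure a spread that may be technical. Tests across genes, such as Fisher's, measure no spread between samples. The authors' q-values did not always follow that spread, as for S100a9 below.

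Expression was given as FPKM (fragments per kilobase of gene, scaled to library size) for each library, as made by the authors with TopHat2 and Cuffdiff on mm9, per the submitters' processing notes. Tool versions, the gene annotation, strandedness and the library normalization are not given in the sources used here. The authors' deposited table also holds a p-value and a q-value per gene for wild type against knockout. Of its 24354 gene symbols, 9204 had a deposited p-value under 1 and were taken as tested; Benjamini-Hochberg adjustment over them gave the deposited q-values within 0.000109. Every tested gene had a group mean of at least 1.94 FPKM in the higher group, and 1630 untested genes had an FPKM of 1 or more in a group, so those genes have no call.

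The peak lists give, per the submitters' processing notes, HDAC3 peaks made with Bowtie and HOMER on mm9. Each list belongs to 1 library, and whether the peaks were called on that library alone is not given in the sources used here. The names of the lists state a minimum of 1 RPM (reads scaled to library size) and filtering by the knockout, neither of which could be tested on the lists. The series holds a knockout ChIP-seq library at ZT10 only, so a filter of the ZT22 list had no knockout library of its own time. Each peak is 150 bp long and carries a score by the authors, whose scale is not given in the sources used here. At ZT10, 99.7% of scores were whole multiples of 1.099 within a tolerance of 0.05 score units, and at ZT22 100% were whole multiples of 1.025 by the same tolerance. The lowest score was 14.3 in both lists. Coordinates are those of mm9, counted from 1.

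Read numbers are not given in the files. Relative depth was therefore taken from genes under 0.3 FPKM, whose values are small whole multiples of what 1 fragment is worth. Against wild-type replicate 1, between 87.3% and 90.3% of the ratios of such genes lay within 0.01 on the log2 scale of a ratio of small whole numbers, against 0.872% to 1.44% at shifted positions. By this measure the depth of wild-type replicates 2 and 3 was 0.831 and 1.02 times that of wild-type replicate 1, and that of knockout replicates 1, 2 and 3 was 0.660, 0.832 and 0.674 times. The shallowest libraries are thus knockout replicates 1 and 3, and low genes are measured less precisely in them. The factor includes any scaling Cuffdiff applied. Genes were not converted to counts, so no counting interval is given for expression.

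A gene was called when its q-value in the authors' deposited table was under 0.05. The design written before the table was seen had assumed 1 value per group with gene positions; the table holds values per replicate and no positions. The planned test was kept, and limma with a mean-variance trend on log2(FPKM + 1) of the tested genes was added beside it (two-sided, Benjamini-Hochberg over 9204 genes). Fold changes are ratios of group means of FPKM, knockout over wild type, with a standard error from the spread of the 3 libraries of each group (delta method); those of limma are on the log2(FPKM + 1) scale, which understates the change of low genes. In simulated data on the 9204 genes with 3 against 3 libraries, limma recovered 20.0%, 62.0%, 78.0% and 80.0% of genes changed 1.5-, 2-, 3- and 4-fold, with 3 false calls.

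The 26 gene lists (pathways, fibre types and markers of other cell types) were fixed before the data were examined, as were the threshold, the tests of the planned comparisons and the rule for named genes. For each list, the shares of members that rose and fell were set against all other tested genes with Fisher's exact test (two-sided, Benjamini-Hochberg over 52 tests). The list's median log2 fold change was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, with a two-sided p adjusted over the 26 lists. Genes are not independent replicates, so both tests describe these libraries. Limma's camera was added with a preset correlation of 0.01 and with a correlation estimated from the libraries. Limma's fry was also run, which tests a list's members across the libraries without comparing them with other genes. Both tests were tried on 200 simulated lists of 20 genes shifted by 1 on the log2 scale, with fold changes shuffled among genes. At an unadjusted 0.05 both found all 200, and the median test called 13 and Fisher's test 11 of 200 lists without a shift. Fisher's test there took a log2 fold change above 1 as a rise in place of the q-value, so its recovery was built in. Shuffling removed correlation between genes, and the largest median of the real lists was 0.90. The simulation thus does not give the power or error of the tests on the real lists.

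Peak lists were compared by overlap of at least 1 bp, with Wilson 95% intervals that cover counting error only, and with 100 random placements of the peaks. Placements were uniform over each chromosome's span of peaks and took no account of genes or open chromatin. An excess over them is thus not particular to HDAC3. Each time has 1 ChIP library, so a difference between the lists has no replicate check.

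The named genes are Hdac3, every measured core clock member, the 8 risen and 8 fallen genes with the largest fold change among called genes at 5 FPKM or more in the higher group and above 0 in both (predicted and small RNA genes left out), and up to 4 called members of each list with the largest fold change, or 2 members where none was called. Some genes that this rule takes are not reported here by name, while counts include them. Of the peaks, the 3 highest-scoring of each list are named. Assigning peaks to genes was planned and not done: no mm9 annotation was at hand, and coordinates were not converted between builds. Neighbouring genes were taken only by their order in a RefSeq gene table of GRCm38.p6, in which 8803 of the 9204 tested symbols (95.6%) were found. Alternatives included other q thresholds, FPKM filters, a minimum fold change, centring, the pseudocount, a replicate block, leaving out each replicate, limma calls, camera, and for peaks the overlap rule, a score minimum and equal list lengths. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.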

Results

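HDAC3, the catalytic subunit of the NCoR/SMRT corepressor complexes, was mapped by ChIP-seq in mouse quadriceps at 2 times of day, and gene expression was measured by RNA-seq with and without HDAC3. Zeitgeber time (ZT) counts hours from lights on, so ZT10 falls late in the light phase and ZT22 late in the dark phase. The RNA-seq comparison had 3 wild-type and 3 knockout libraries at ZT10. The ChIP-seq lists came from 1 wild-type library at each time. FPKM values summed to between 454359 and 495099 per library, and between 10281 and 10544 genes reached 1 FPKM. Tnnt3, fast skeletal troponin T, was the most abundant gene in each library, and the 10 most abundant genes held 21.4% to 24.4% of the FPKM sum. The depth of knockout replicates 1 and 3 was 0.660 and 0.674 times that of wild-type replicate 1, and that of the other 3 libraries lay between 0.831 and 1.02 times. Pearson correlations of log2(FPKM + 1) across tested genes, which are not independent replicates, were 0.961 to 0.972 within groups and 0.947 to 0.957 between them. Values below are mean FPKM ± SD (n = 3 libraries per group), wild type before knockout, and log2 fold changes ± SE are knockout over wild type.

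Hdac3 itself was examined first, as a check of the labels. It fell from 29.3 ± 4.99 to 6.65 ± 1.36 FPKM, a 4.41-fold difference (log2 fold change -2.14 ± 0.22). The wild-type libraries gave 33.3, 31.0 and 23.7 FPKM and the knockout libraries 5.51, 6.29 and 8.16, so the groups did not overlap. The q-value in the authors' deposited table was 0.00119, the lowest it holds, which 386 tested genes share. The adjusted p of limma was 0.00487. Reads in the knockout can come from exons left in place or from cells in which the gene was not deleted, and FPKM per gene cannot separate these.

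Loss of HDAC3 was accompanied by changes in 998 of 9204 tested genes (10.8%), of which 543 rose and 455 fell. The median change of a called gene was 1.64-fold for risen and 1.71-fold for fallen genes, while 126 rose and 112 fell by 2-fold or more. Among the genes with the largest rise, Mthfd2, a mitochondrial enzyme of folate metabolism, went from 1.80 ± 0.479 to 37.5 ± 12.2 FPKM (20.8-fold), and Cdkn1a, which encodes the cell cycle inhibitor p21, from 1.17 ± 0.360 to 13.3 ± 3.84 (11.3-fold). Tlcd2 rose 10.6-fold to 9.36 ± 2.43 and Fgfbp1, a fibroblast growth factor carrier, 6.08-fold to 14.9 ± 5.10. Mybph, a myosin-binding protein, rose 8.55-fold to 42.1 ± 28.2, the adenosine receptor gene Adora1 8.80-fold to 6.42 ± 4.93 and the immediate early gene Fos 9.69-fold to 21.3 ± 21.9. Single libraries moved some of these folds: without wild-type replicate 1 Mybph rose 18.6-fold, Adora1 20.7-fold and Fgfbp1 9.42-fold, without knockout replicate 2 Mybph 5.24-fold and Adora1 4.90-fold, and without knockout replicate 3 Fos 3.95-fold. Srrm4os showed the largest fold of the named genes, from 0.234 ± 0.0770 to 10.4 ± 2.56 FPKM. It is an antisense transcript, and since strandedness is not given its reads cannot be told from those of a partner on the other strand.

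The genes with the largest fall included Actr3b, an actin-related protein (8.15 ± 1.31 to 1.28 ± 0.562 FPKM, 6.37-fold), the peptide transporter gene Slc15a5 (6.85 ± 2.29 to 1.32 ± 0.350, 5.20-fold) and Map3k7cl (5.96 ± 2.04 to 1.19 ± 0.380). Gamt, which makes creatine from guanidinoacetate, went from 5.49 ± 0.913 to 0.807 ± 1.13 FPKM (6.80-fold); its knockout libraries were at 0.330, 2.09 and 0 FPKM, and without knockout replicate 2 the fold was 33.3. Actc1, cardiac actin, fell 9.21-fold from 131 ± 140, with wild-type libraries at 292, 68.3 and 32.6 FPKM and knockout libraries at 13.5, 20.4 and 8.71, and without wild-type replicate 1 the fold was 3.55. S100a8 and S100a9, abundant in neutrophils, were called as fallen, yet their wild-type means rested on replicate 2, at 240 and 222 FPKM. The other wild-type libraries held 1.79 and 4.37 FPKM of S100a8 and 3.11 and 5.06 of S100a9, against 2.15 to 2.70 and 0.767 to 4.70 in the knockout. Without wild-type replicate 2 their log2 fold changes were -0.30 and -0.87.

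Among the called genes, 464 of the 543 risen genes (85.5%) and 362 of the 455 fallen genes (79.6%) had every knockout library on the same side of every wild-type library. The calls rest on the same libraries, so this describes them and is no separate support for them. All 998 called genes had the same sign in limma, which called 434 genes (280 rose, 154 fell), 393 of them shared with the calls above. Of the 82 named genes with a call, here and in the lists, 39 were also called by limma. Of the genes just named, Fos, Adora1, Actc1, S100a8 and S100a9 were not called by limma, with adjusted p of 0.0762, 0.0564, 0.0894, 0.456 and 0.325. The number limma called fell to 20 without wild-type replicate 2, 54 without knockout replicate 3, 82 without knockout replicate 1, 195 without knockout replicate 2 and 269 without wild-type replicate 1.

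**Figure D1:**
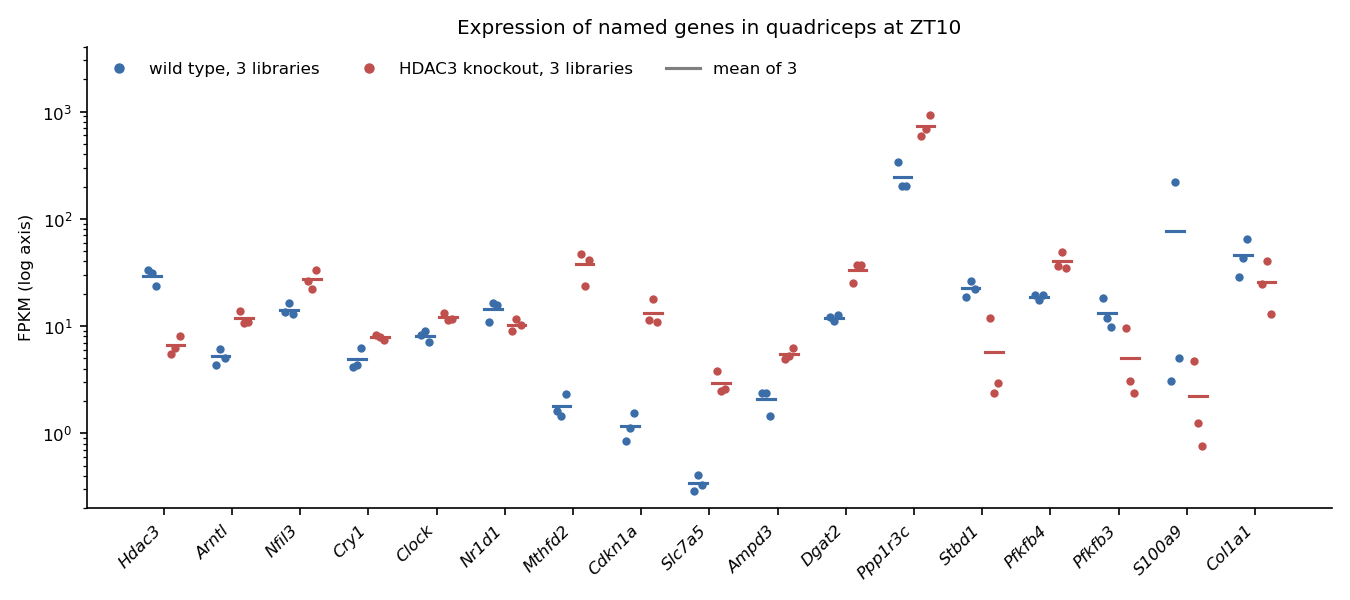
FPKM on a log axis for 17 named genes in quadriceps at ZT10; points are the 3 wild-type (blue) and 3 knockout (red) libraries, and lines are group means. Mthfd2 lies between 23.8 and 47.2 FPKM in the knockout against 1.44 to 2.35 in wild type, whereas the wild-type mean of S100a9 rests on the single library at 222 FPKM.

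Since HDAC3 acts in the circadian clock with the nuclear receptors Rev-erb alpha and beta, the core clock genes were asked about next. All RNA libraries were taken at ZT10, so for these rhythmic genes a change of level cannot be told from a shift of timing. Of 18 measured members, 4 rose, 1 fell and 13 were not called (6 rose and 2 fell when adjusted over the list alone). Arntl, which encodes BMAL1, rose 2.27-fold from 5.21 ± 0.910 to 11.8 ± 1.70 FPKM, and Nfil3, a repressor of D-box genes, 1.93-fold from 14.2 ± 1.87 to 27.4 ± 5.77. Cry1 rose 1.61-fold and Clock 1.48-fold; the adjusted p of limma was 0.0162 for Arntl and 0.0297 for Nfil3, and 0.0693 and 0.0564 for Cry1 and Clock. Nr1d1, which encodes Rev-erb alpha, was at 14.3 ± 2.95 and 10.3 ± 1.31 FPKM and was not called. Log2 fold changes of the other uncalled members were 0.42 ± 0.09 for Cry2, 0.39 ± 0.60 for Per1, -0.38 ± 0.09 for Bhlhe41, 0.37 ± 0.15 for Tef, 0.36 ± 0.71 for Ciart, 0.20 ± 0.08 for Rora, -0.16 ± 0.24 for Per3, 0.09 ± 0.26 for Dbp, -0.07 ± 0.30 for Hlf and 0.06 ± 0.24 for Per2, with Bhlhe40 and Nr1d2 at 0.00. Without wild-type replicate 1 the knockout was higher in Ciart by 2.36-fold, and the signs of Ciart, Per1, Dbp, Hlf, Per2, Bhlhe40 and Nr1d2 turned when some single library was left out. The share of risen members, 22.2% against 5.87% of other tested genes, did not pass (Fisher's exact test, adjusted p = 0.109), nor did the list's median of 0.14 (adjusted p = 0.272, and 0.0253 without knockout replicate 1). Among the corepressor partners, 2 of 11 rose, both of them TBL1 proteins: Tbl1xr1 by 1.72-fold and Tbl1x by 1.60-fold (share adjusted p = 0.368).

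Fuel metabolism was taken list by list. For glucose, 3 of 19 uptake and glycolysis genes rose and 1 fell: Pfkfb4 rose 2.13-fold to 40.1 ± 7.70 FPKM while Pfkfb3, which encodes another isozyme of the same regulator of glycolysis, fell 2.67-fold to 5.01 ± 3.95 (4.88-fold without knockout replicate 1), and Hk2 and Gpi1 rose 1.48- and 1.37-fold. In glycogen metabolism 3 of 16 rose and 1 fell. Ppp1r3c, which targets protein phosphatase to glycogen, rose 2.98-fold from 248 ± 79.9 to 737 ± 177 FPKM, the branching enzyme gene Gbe1 1.78-fold, and glycogenin (Gyg) went from 192 ± 3.64 to 288 ± 50.2; Stbd1, which tethers glycogen to membranes, fell 3.90-fold from 22.4 ± 3.86 to 5.75 ± 5.38 (8.46-fold without knockout replicate 1). Around pyruvate dehydrogenase, 2 of 13 rose and 2 fell: the phosphatase gene Pdp2 rose 2.37-fold and the carrier gene Mpc1 1.42-fold, and the kinase genes Pdk4 and Pdk1 each fell 1.56-fold. Pdk4 overlapped between the groups, at 149 ± 65.5 and 95.3 ± 29.7 FPKM, whereas Pdk1 did not, at 24.7 ± 1.07 and 15.8 ± 0.283. None of these 3 lists passed for the share risen (adjusted p of 0.340, 0.279 and 0.415) or for the median (0.376, 0.987 and 0.227). By camera the glucose list passed with a preset correlation (adjusted p = 0.0352) and did not with an estimated correlation (adjusted p = 0.607). Of the genes named here, limma also called Pfkfb4, Ppp1r3c, Gbe1 and Pdk1; the adjusted p was 0.0541 for Stbd1 and 0.111 for Pfkfb3.

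Fatty acid uptake and oxidation genes lay higher as a list, with a median log2 fold change of 0.27 and 22 of 28 members higher. Random lists of like expression had a median of 0.08, against which the adjusted p was 0.0247. With an estimated correlation the adjusted p of camera was 0.743, and the adjusted p of the median was 0.512 without wild-type replicate 3 and 0.0689 without knockout replicate 3. Called members were 5 risen and 2 fallen (9 and 2 when adjusted over the list alone), a share of 17.9% that did not pass (adjusted p = 0.116, and 0.00292 at a q threshold of 0.1). Echs1, enoyl-CoA hydratase, rose 2.02-fold to 151 ± 29.2 FPKM and Acsl1, which activates fatty acids, 1.42-fold, while Acads, the short-chain dehydrogenase, fell 1.76-fold and the uncoupling protein gene Ucp3 1.53-fold. Lipid synthesis and storage had 5 risen and 1 fallen of 22, led by Dgat2, which makes triglyceride (12.0 ± 0.764 to 33.0 ± 6.60 FPKM, 2.76-fold), with Plin5 up 1.73-fold, Acaca up 1.64-fold and Mlxipl down 1.63-fold; the median of 0.22 had an adjusted p of 0.0562. In the tricarboxylic acid cycle 2 of 18 rose, among them Idh2 by 2.30-fold to 195 ± 26.6 FPKM. Of 42 oxidative phosphorylation genes none rose and 1 fell, Atp5g1 by 1.36-fold; limma called none of the 42 (adjusted p = 0.228 for Atp5g1), and at an unadjusted p under 0.05 the authors' deposited table had 1 risen and limma 3. The median of the oxidative phosphorylation list was 0.03. Random lists of like expression had a median of 0.11, against which the list did not pass (adjusted p of the median = 0.249). Among regulators of mitochondrial biogenesis 4 of 16 rose: Esrrg, an orphan nuclear receptor, by 2.19-fold, Tfam, the mitochondrial transcription factor, by 1.79-fold, Foxo3 by 1.66-fold and Foxo1 by 1.59-fold (share adjusted p = 0.0853). Of the genes named here, limma also called Echs1, Dgat2, Idh2, Esrrg and Tfam.

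Branched-chain amino acid breakdown had 4 risen and no fallen genes of 23 (at an unadjusted p under 0.05, none fallen in the authors' deposited table and 1 by limma), with 18 higher and a median of 0.22 (adjusted p = 0.0661, and 0.0165 without wild-type replicate 1). Random lists of like expression had a median of 0.05. By camera the branched-chain list passed with a preset correlation (adjusted p = 0.0352) and did not with an estimated correlation (adjusted p = 0.611). Dbt, a subunit of the branched-chain ketoacid dehydrogenase, rose 1.96-fold to 20.2 ± 3.50 FPKM, Pcca 1.85-fold, Ivd 1.78-fold and Ppm1k 1.46-fold. Other amino acid metabolism had 6 risen and 1 fallen of 21 (7 and 1 when adjusted over the list alone), and its risen share of 28.6% against 5.85% passed (Fisher's exact test, adjusted p = 0.0180). Its median of 0.18 did not (adjusted p = 0.222, and 0.0193 without wild-type replicate 1), nor did camera (adjusted p = 0.157 with a preset and 0.607 with an estimated correlation, which was -0.012). By fry the list passed (adjusted p = 0.00850). The call of the share ended at a q threshold of 0.1 (adjusted p = 0.0536) and with calls by limma (0.0664). Of 28 listed genes 21 were tested, and every tested gene reached 1.94 FPKM in its higher group. Slc7a5, Asns and Aldh18a1 lay under that in wild type (0.341, 0.744 and 1.56) and entered through the knockout alone. Listed genes low in both groups could not count, so this limit may raise the share. The amino acid transporter gene Slc7a5 rose 8.64-fold from 0.341 ± 0.0591 to 2.95 ± 0.729 FPKM, asparagine synthetase (Asns) 4.48-fold, glutamine synthetase (Glul) 2.78-fold to 343 ± 116 and Aldh18a1, of proline synthesis, 2.24-fold. In the purine nucleotide cycle 1 of 14 rose and 2 fell: Ampd3, an AMP deaminase, rose 2.65-fold from 2.07 ± 0.539 to 5.49 ± 0.678 FPKM, and Nt5c1a and Ak1 fell 1.81- and 1.43-fold. Gamt was the only called gene of 4 in creatine metabolism. Of the genes named here, limma also called Dbt, Pcca, Ivd, Slc7a5, Glul, Ampd3 and Gamt.

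Atrophy genes and stress genes stood furthest apart from random lists. Of 17 atrophy genes 7 rose and none fell (10 and 0 when adjusted over the list alone, and 0 fallen at an unadjusted p under 0.05, also by limma), with a median of 0.48 (adjusted p = 0.00260, the smallest the 10000 lists allowed here). With an estimated correlation, which at -0.030 was below the preset 0.01, camera gave an adjusted p of 0.124. Fry gave an adjusted p of 0.00586 for this list and 0.0710 for the stress genes below. Beside Cdkn1a, Ddit4 rose 2.90-fold, the lysosomal protease gene Ctsl 2.33-fold to 71.6 ± 8.73 FPKM and Eif4ebp1, a repressor of translation, 2.07-fold to 55.3 ± 1.97. Of 11 immediate early and stress genes 6 rose and 1 fell, with a median of 0.90 and the same adjusted p of 0.00260, against an adjusted p of 0.607 by camera with an estimated correlation. Beside Fos, Sesn2 rose 4.17-fold, the transcription factor gene Atf3 3.15-fold and Psat1, of serine synthesis, 2.89-fold; Atf3 was at 39.4, 2.17 and 44.8 FPKM in the knockout libraries against 3.34, 15.3 and 8.83. The fold of Atf3 was 4.74 without wild-type replicate 2 and that of Psat1 1.84 without knockout replicate 1. Of the genes named here, limma also called Cdkn1a, Ctsl, Eif4ebp1 and Sesn2. The risen shares, 41.2% and 54.5%, each had an adjusted p of 0.000720 by Fisher's exact test. With calls by limma both had an adjusted p of 0.0664. All 17 listed atrophy genes were tested, but only 11 of 20 listed stress genes. Sesn2 and Psat1 lay at 0.491 and 0.836 FPKM in wild type, under the 1.94 FPKM that every tested gene reached in its higher group. They thus entered through the knockout alone, and stress genes low in both groups could not count. This limit may raise the share and the median of the stress list.

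**Figure D2:**
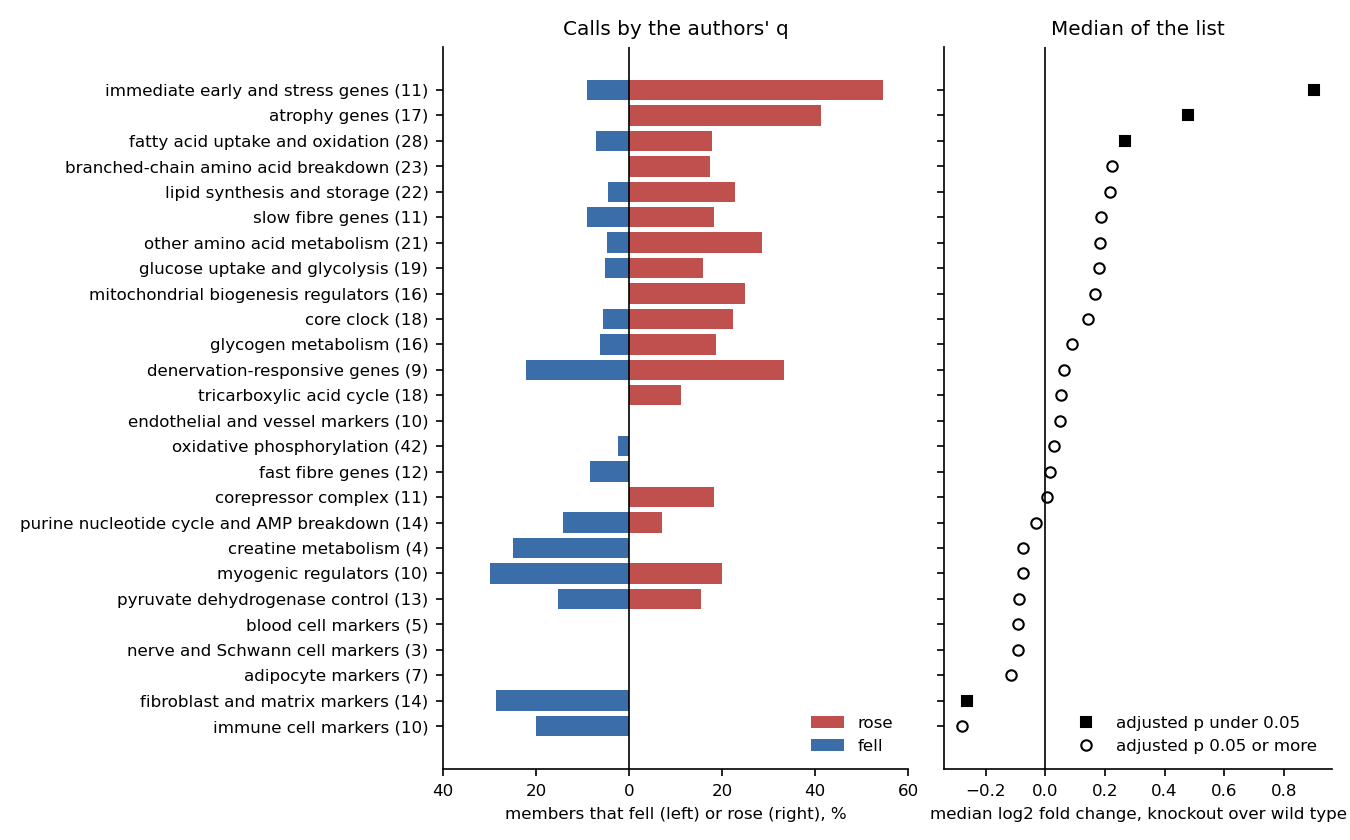
Left, the percentage of measured members (number in brackets) of each of 26 gene lists that fell (blue) or rose (red) by the authors' q; right, the list's median log2 fold change, with filled squares for an adjusted p under 0.05 against random lists. Atrophy and stress genes lie at medians of 0.48 and 0.90 and matrix markers at -0.26. Medians of the random lists of like expression lay between -0.03 and 0.11, so the vertical line on the right is not their baseline.

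Fibre type, innervation and myogenic genes changed individually in both directions. Among fast fibre genes 1 of 12 fell, the myosin light chain gene Myl1 by 1.56-fold, and of 11 slow fibre genes Mybpc1 and Myl3 rose 1.53- and 1.47-fold while Casq2 fell 1.72-fold. Denervation-responsive genes had 3 risen and 2 fallen of 9: Myog rose 2.50-fold and the acetylcholine receptor gene Chrne 1.86-fold, whereas Musk, of the neuromuscular junction, fell 1.98-fold and Chrnb1 1.76-fold. Of 10 myogenic regulators 2 rose and 3 fell; beside Myog, desmin (Des) rose 1.93-fold to 960 ± 120 FPKM, and Eya1 fell 2.31-fold to 3.70 ± 0.263 and Cdh15, of satellite cells, to 1.72 ± 0.422 from 3.45 ± 1.19. No share or median of these 4 lists passed, the lowest adjusted p being 0.0853. With 1 library left out some medians did: slow fibre genes without knockout replicate 1 (adjusted p = 0.00728) or wild-type replicate 1 (0.00173), and denervation-responsive genes without wild-type replicate 3 (0.00390). Of the genes named here, limma also called Musk, Chrne, Chrnb1, Des and Eya1.

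Markers of other cell types were measured because whole muscle holds them. Fibroblast and matrix markers lay lower, with 13 of 14 members below wild type, 4 fallen and a median of -0.26 (adjusted p = 0.0121). With an estimated correlation camera gave an adjusted p of 0.743. Col1a1 fell 1.76-fold from 45.7 ± 18.4 to 26.0 ± 13.7 FPKM, Col1a2 1.55-fold, Postn 1.43-fold and Col5a1 1.41-fold, and none was called by limma. Knockout replicate 3 carried most of this: its median over the list, relative to the wild-type mean, was -0.68, against -0.05 and -0.16 in knockout replicates 1 and 2, and without it the list's median was -0.088 (adjusted p = 0.337). The fold of Postn was 2.71 without knockout replicate 2 and 1.04 without knockout replicate 3. Leukocyte markers had 9 of 10 members below wild type and a median of -0.28 that did not pass (adjusted p = 0.0598), with S100a8 and S100a9 as the 2 called. The adjusted p was 0.00260 without knockout replicate 1, 0.0114 without wild-type replicate 1 and 0.0458 without wild-type replicate 2; relative to the wild-type mean the list's median was -0.017, -0.54 and -0.47 in the knockout libraries and -0.21, -0.061 and 0.098 in the wild-type libraries. No endothelial and vessel, adipocyte, nerve or blood marker was called, of 10, 7, 3 and 5 measured. Their medians were 0.05, -0.11, -0.09 and -0.09. Against random lists that of the blood markers passed without knockout replicate 2 (adjusted p = 0.0468). Limma called none of these markers either. At an unadjusted p under 0.05 it had 1 endothelial or vessel marker, and the authors' deposited table had 2 adipocyte markers, 1 in each direction. When adjusted over the list alone, 1 adipocyte marker rose and 1 fell. Tagln and Vwf had log2 fold changes of 0.52 ± 0.13 and -0.29 ± 0.27, Cfd and Lpl -0.63 ± 0.76 and 0.44 ± 0.31, Pmp22 and Mbp -0.20 ± 0.20 and -0.09 ± 0.14, and Hbb-bs and Hba-a1 -0.52 ± 1.21 and -0.46 ± 0.60. Without knockout replicate 1 the knockout was lower in Cfd by 2.95-fold and in Hbb-bs by 3.25-fold, and without wild-type replicate 3 it was higher in Hbb-bs by 1.37-fold; the signs of Hba-a1, Mbp and Pmp22 also turned when a single library was left out. The globin genes are near-identical copies, between which reads can be split differently from library to library.

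HDAC3 binding was compared between times of day by its peak lists. At ZT10 the list held 4093 peaks and at ZT22 1459, a ratio of 2.81 that lay between 2.40 and 3.24 on every autosome. The 150 bp peaks overlapped at 710 places, which is 17.3% of the ZT10 peaks (95% Wilson interval 16.2% to 18.5%) and 48.7% of the ZT22 peaks (46.1% to 51.2%), while 100 random placements gave a median of 1 overlap and at most 3. Thus 3383 peaks were listed at ZT10 alone and 749 at ZT22 alone. Peaks with high scores were shared more often: with each list divided by score into 4 groups of like size, 35.8% in the highest and 5.18% in the lowest group at ZT10, and 69.8% and 34.2% at ZT22. The score, given by the authors, had a median of 18.7 at ZT10 (14.3 to 160.5) and 17.4 at ZT22 (14.3 to 117.9). Many peaks lay close to others, with 24.1% of ZT10 peaks and 12.8% of ZT22 peaks within 10 kb of another in their list, against at most 4.50% and 2.74% in random placements. These placements were uniform along each chromosome.

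The highest-scoring peak was the same at both times, on chromosome 5 at 132034430 to 132034579 (mm9) with a score of 160.5 at ZT10, and at 132034449 to 132034598 with 117.9 at ZT22. The next ZT10 peaks lay on chromosome 7 at 108651980 to 108652129 (138.5, with no ZT22 peak) and on chromosome 13 at 70729273 to 70729422 (133, with a ZT22 peak of score 41). At ZT22 they lay on chromosome 14 at 32369164 to 32369313 (74.8, with no ZT10 peak) and on chromosome 16 at 20091345 to 20091494 (66.6, with a ZT10 peak of 98.9). Genes at these positions were not assigned, since no annotation of mm9 was used here. Shares depended on the list's length and score minimum: with both lists at 1459 peaks 31.3% were shared, and among peaks of at least 2 times the lowest score (788 and 153) 14.1% of ZT10 and 72.5% of ZT22 peaks were. With 1 library per time and no read numbers, the difference in peak number has no replicate check. The only knockout ChIP-seq library was of ZT10, so filtering by the knockout may also have differed between the lists.

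**Figure D3:**
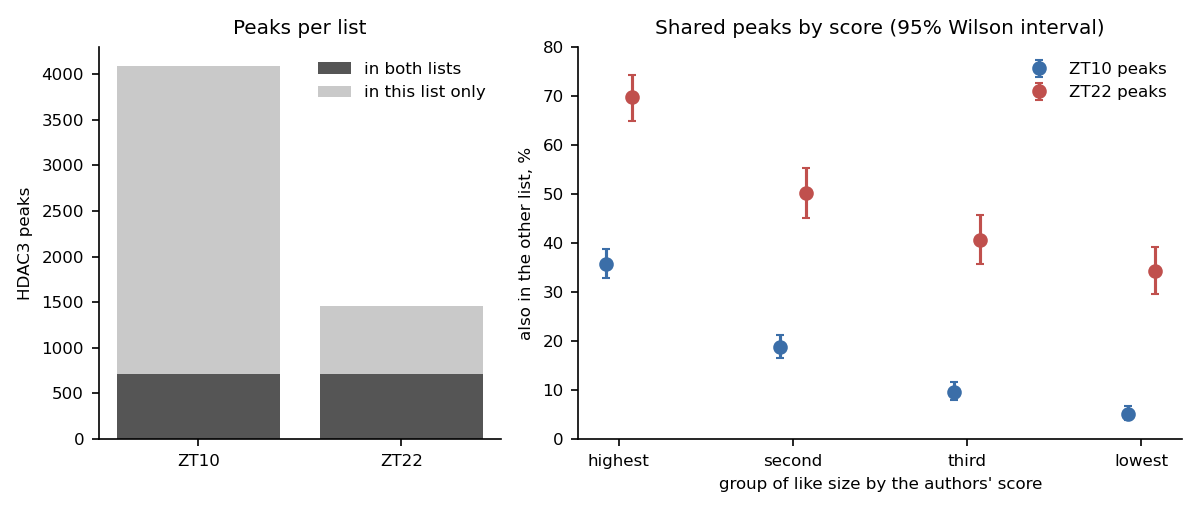
Left, the number of HDAC3 peaks at ZT10 and ZT22, divided into peaks found in both lists (dark) and in that list only (light); right, the percentage of peaks also in the other list in 4 groups of like size by the authors' score, with 95% Wilson intervals. The shared share falls from 35.8% to 5.18% at ZT10 and from 69.8% to 34.2% at ZT22.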

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

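Limma in place of the authors' test, its pseudocount and minimum, camera, an FPKM minimum of 5, list shares with calls by limma, and single libraries or the block in the tests of lists and named genes were chosen after the data were seen. The others were planned, among them the replicate block and leaving out each library for the number of changed genes. The number of changed genes by the authors' q was 605 at a threshold of 0.01 (331 rose, 274 fell), 1328 at 0.1, 756 with a 1.5-fold minimum, 857 at 5 FPKM or more and 998 after centring, which turned no direction. A minimum of 1 FPKM removed no tested gene. By limma it was 434 (280 rose, 154 fell), 427 with a pseudocount of 0.1 and 450 at 5 FPKM or more. Same-numbered libraries showed little common deviation (correlations of -0.00, 0.05 and 0.05), and not every library correlated best with its own number. These few values show no pairing by number and cannot exclude a weak one. With replicate number as a block, limma called 52. Leaving out 1 library gave 20 (without wild-type replicate 2) to 292 calls, with fewer samples in each fit.

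With calls by limma, fewer in number, the adjusted p of the risen share was 0.0664 for atrophy, stress and other amino acid genes; at a q threshold of 0.1 that of the last was 0.0536, for a cause not tested. Across other alternatives it ran from 6.69e-05 to 0.000720 for atrophy and from 0.000720 to 0.00178 for stress genes. With an estimated correlation, camera's adjusted p was 0.124 for atrophy, 0.607 for stress, 0.743 for fatty acid and 0.743 for matrix genes. Its preset correlation of 0.01 kept all 4. The estimated correlation was -0.030 for atrophy genes, so a higher correlation did not end their call. For stress, fatty acid and matrix genes it was 0.18, 0.29 and 0.36. Fry, also chosen after the data were seen, gave adjusted p of 0.00586 for atrophy and 0.00850 for other amino acid genes. For stress, fatty acid and matrix genes fry gave 0.0710, 0.168 and 0.458. Leaving out 1 library, the median's adjusted p ran from 0.0114 to 0.512 for fatty acid genes and from 0.00173 to 0.337 for matrix markers, and reached at most 0.00520 for atrophy and stress genes. Counting each of the 26 lists once per setting, passing shares lost their call 4 times and passing set tests (median or camera) 7 times, and 1 and 12 others gained one; of 56 passing results 0 turned direction, and of 438 others 43 did. Of 82 named genes with a call, 39 were also called by limma and 11 with the block; none changed sign.

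The share of peaks in the other list was 14.4% of ZT10 and 40.5% of ZT22 peaks when each had to overlap by 50%, 17.9% and 50.2% for centres within 200 bp, 31.3% at equal list lengths, and 14.1% and 72.5% among peaks of at least 2 times the lowest score, of which there were 788 and 153. Not run were peaks near changed genes and gene lists near peaks (no mm9 annotation was used) and p-values from a test statistic (the table holds none). Read numbers are unknown, and knockout replicates 1 and 3 are the shallowest RNA libraries.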

Other observations

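The tests of single libraries, of non-muscle cells, of the X chromosome and of other splits of the libraries were chosen after the result was seen. Lists of textbook ATF4, p53 and NRF2 target genes, leaving out the genes of the 26 lists and genes whose values had been seen, were written after the rise of stress genes was seen and before their own members were tested.

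Of 23 measured genes of the ATF4 list, 9 rose and none fell (2 fallen at an unadjusted p under 0.05 in the authors' deposited table, 0 by limma), with 19 higher and a median log2 fold change of 0.38. The risen genes included 6 of the 12 measured aminoacyl-tRNA synthetase genes of the list, Gars (34.6 ± 1.41 to 69.4 ± 11.8 FPKM; SD, n = 3), Eprs (108 ± 11.2 to 204 ± 26.2), Nars (44.4 ± 4.36 to 74.2 ± 3.75), Lars, Aars and Yars, while Mars, Tars, Sars, Iars, Cars and Wars were not called, and also Herpud1, Cebpg and Cebpb; limma called 7 of the list as risen. Of 17 p53 targets 4 rose, Btg2, Eda2r, Phlda3 and Trp53inp1, none of them called by limma. At an unadjusted p under 0.05 limma had 3 of the list as risen and 2 as fallen, and the authors' deposited table also had 2 as fallen. Of 23 NRF2 targets 5 rose, Ftl1, Cat, Gstm1, Ephx1 and Txnrd1, and Aox1 and Cbr1 fell; limma called 3 as risen. These genes were named because of their lists, after their values were seen.

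A single high knockout library as the source of the rise of atrophy and stress genes is argued against by the medians over all members of these lists, which still passed against random lists when each knockout library was left out in turn (adjusted p at most 0.00520). For other amino acid genes this stays open, since their median passed neither with all libraries (adjusted p = 0.222) nor without any 1 knockout library (0.0555 to 0.154). ATF4 activity is a candidate explanation: the held-out list had a risen share of 39.1% against 5.82% (Fisher's exact test, p = 3.14e-06), and its median had the smallest p the random lists can give (0.000200, adjusted 0.000600). The risen shares of the p53 and NRF2 lists passed too, with p of 0.0154 and 0.00973 (adjusted 0.0154 and 0.0146), but their medians of 0.15 and 0.18 did not pass against random lists (adjusted p = 0.113 and 0.0693), so evidence was strongest for the ATF4 list without excluding the others, and genes within such lists are correlated. Whether HDAC3 loss acts on these regulators directly stays open, since peaks were not assigned to genes.

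The fall of the matrix markers may reflect the makeup of single tissue pieces; the leukocyte list passed no test with all libraries (adjusted p of its median = 0.0598). A loss of every non-muscle cell type is argued against by the endothelial and vessel markers, whose median lay above that of the matrix markers. The difference, matrix minus endothelial and vessel, was -0.31 (permutation p across genes = 0.00194). It did not pass without knockout replicate 3 (-0.14, permutation p = 0.0726) or wild-type replicate 1 (-0.22, permutation p = 0.141). The endothelial and vessel list also holds genes of the vessel wall such as Tagln, so it does not measure endothelial cells alone. The fall of the matrix list may be carried by knockout replicate 3, without which its median was -0.088. Neutrophil RNA in wild-type replicate 2 is a candidate source of S100a8 and S100a9, whose log2 fold changes were -0.30 and -0.87 without it. A change of fibroblasts or leukocytes with HDAC3 loss stays open and untested.

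HDAC3 peaks were sparse on the X chromosome, with 38 at ZT10 and 6 at ZT22. Per megabase this was 14.1% of the autosomal median at ZT10 (95% counting interval 9.98% to 19.4%) and 6.51% at ZT22 (2.39% to 14.2%). A candidate explanation is that male mice have 1 X chromosome, so that scores there would be lower and more peaks would miss the score minimum: 19.1% of autosomal ZT10 peaks and 10.5% of ZT22 peaks had at least 2 times the lowest score, and both lie within those intervals. Gene density and muscle-expressed genes on the X chromosome were not tested, so a lower HDAC3 occupancy there stays open.

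Of the 10 splits of the 6 RNA libraries into 3 and 3, only 1, the real split, called as many genes by limma (434), and the highest of the others called 2. With 10 splits the share cannot go under 0.1. Of the 40 tested genes nearest to Hdac3 by gene order, 8 were called (20%), against 10.8% of all tested genes (Fisher's exact test, p = 0.0720). The ZT10 list held 5 runs of 5 or more neighbouring peaks, among them 6 peaks on chromosome 7 between 119885347 and 119907299 (mm9) and 6 on chromosome 3 between 108013001 and 108029712, with 5 and 2 peaks at ZT22.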
